A study of Arabidopsis thaliana with 12 samples.

How the data were processed

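RNA levels were measured in 12 samples, 6 from plants in darkness overnight and 6 from plants in light for 1 h after the night, and the groups and replicate numbers were taken from the sample labels. The labels do not say whether the samples of a group are separate plants, so p-values measure the spread between these samples, which may be technical.

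The deposited table holds 1 intensity per probe and array on a linear scale whose top is 100, with up to 5 spots of an array at that top. How the authors made these values, including scanning, background subtraction and scaling, is not given in the sources used here. Between 11.7 and 15.7% of the deposited values of an array were exactly 0. The highest column sum was 1.25 times the lowest and the highest column median 1.42 times the lowest. The table therefore did not count as normalized under a rule fixed before the data were examined, which allowed 5%. The medians of the 12 columns ran from 0.204 to 0.289.

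Arrays were quantile normalized, values below the 1% quantile of positive deposited values (0.0067) were set to it, and log2 was taken. Probes at that floor in more than 6 of 12 arrays were left out, which removed 473 of 3439 probes and left 2966. Light was compared with dark in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, two-sided, and p-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Gene lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, and figures were drawn with matplotlib 3.10.9. On simulated data for 1 h light against dark with 3316 probes run, the fit recovered 66 of 100 probes changed by 1 on the log2 scale and 83 of 100 changed by 2, with 10 false calls among 3116 unchanged probes. False calls were 6.3% of the simulated calls. The simulated columns had independent noise and few changed probes, whereas the real columns were alike in pairs, as described below. The simulation therefore does not give the error rate in the real data.

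Gene names came from the platform annotation, which is old, matched by gene identifier to a gene table of the TAIR10.1 assembly. It lists 1 gene for 692 probes (690 matched, 2 not) and several for 870, while 1877 are not named here. No gene was named from a probe with several, and such probes are given by list where all their genes belong to 1. The genome build behind the array is not given in the sources used here, so no coordinates are printed. The 24 gene lists fixed before the data were examined hold 392 loci, of which 19 are on single-gene probes. Lists for aminoacyl-tRNA synthetases and pentatricopeptide repeat proteins were to be filled from annotation text, which was not given, and stayed empty.

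The text names the 12 largest rises and 12 largest falls among single-gene probes that passed and had all 6 light values on the same side of the dark mean, and up to 4 members of each list. None of 15 light-response genes and 6 housekeeping genes set in advance was on a tested single-gene probe. The brighter genes and 3 further lists were chosen after the values were seen.

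Replicate numbers are shared between the groups. Deviations from the group means correlated between the dark and light columns of a number at 0.301 to 0.557 over 1483 probes. Each dark column correlated best with the light column of its own number. For number 3 the margin over the number of its pair partner was small (0.301 against 0.257), so pairing by single number is not settled. Such a pairing would come from these values and not from the labels. Within a group the pairing of columns 1 and 2, 3 and 4, and 5 and 6 had the smallest spread of the 15 possible pairings, with a mean SD of 0.401 in dark (lowest other 0.485) and 0.498 in light (lowest other 0.544). The fit on all 12 columns was kept as fixed before the data were examined, and a fit on the 3 pair means per group was added. Alternatives covered the replicate block, other scalings, the floor, the filter on dim probes, the variance model, array weights and leaving out each array. Alternatives added later were the pair means, a random block for pairs, a floor at the 25% quantile, and leaving out each pair of numbers.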

Results

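Transcript levels were measured on arrays in wild-type Arabidopsis thaliana plants of the Columbia-0 accession, the standard laboratory accession. Of the 12 samples, 6 came from plants kept in darkness overnight and 6 from plants given 1 h of light after the dark night. The comparison asked which transcripts differed after 1 h of light. The times of harvest are not given here. With only these groups, an effect of light cannot be told apart from one of time after the night or of handling by group. Each array gave 1 value for each of 3439 probes on a relative intensity scale that ends at 100. The column sums ran from 2943 to 3683, and 11.7 to 15.7% of the values in an array were exactly 0. The number of arrays limits the precision. Levels below are scaled intensities, given as mean ± SD over 3 means of consecutive replicate numbers (n = 3), because columns 1 and 2, 3 and 4, and 5 and 6 of a group resembled repeat measurements. Such an SD leaves out the spread within a pair and can be far smaller than the spread of single arrays. SE and adjusted p-values are from limma on all 12 arrays, taken as separate samples, with Benjamini-Hochberg adjustment, and log2 changes are light minus dark. If the columns of a pair are repeat measurements, these SE and p-values are too small.

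Of 6 genes tested from the photosystem, light-harvesting and Calvin cycle lists, 4 were higher after 1 h of light, 1 was lower and 1 did not pass. Each of these lists had fewer than 5 tested members, so none had a set test, and they were not tested together. PSAN, a subunit of photosystem I on the lumen side, rose from 3.83 ± 0.34 to 9.54 ± 0.78 (log2 change 1.32, SE 0.11, adjusted p = 1.6e-06). LHCB1.5, a chlorophyll-binding antenna protein of photosystem II, rose from 19.1 ± 5.1 to 43.5 ± 6.8 (log2 change 1.22, SE 0.17, adjusted p = 1.5e-04). PRK, the Calvin cycle enzyme that makes ribulose bisphosphate, rose from 0.592 ± 0.166 to 2.49 ± 0.85 (log2 change 2.02, SE 0.26, adjusted p = 6.8e-05). Light replicate 2, at 4.82 against 1.88 to 2.13 in the other light arrays, raised the light mean of PRK. PSBW, a small subunit of photosystem II, fell from 84.2 ± 10.3 to 36.7 ± 5.5 (log2 change -1.20, SE 0.13, adjusted p = 1.5e-05), a call that was lost with arrays centred on the 75th percentile. With the consecutive numbers averaged, PSAN, LHCB1.5, PRK and PSBW passed with larger p-values (limma, adjusted p = 0.0029, 0.016, 0.0078 and 0.0074).

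Over the whole array, 1198 of 2966 probes tested passed an adjusted p of 0.05, 589 higher and 609 lower in light. A change of more than 2-fold was seen in 320 of the higher and 277 of the lower probes. Among the 596 tested probes that match 1 gene, 121 were higher and 134 lower. With the consecutive numbers averaged, which leaves 3 values against 3, 814 probes passed, 406 higher and 408 lower, and 786 of them were among the 1198. The balance of directions depended on how the arrays were scaled. It was 423 higher and 879 lower for the values as deposited (32.5% higher, median log2 change of all probes -0.21), 528 and 821 with arrays centred on their medians (39.1% higher), and 781 and 544 with arrays centred on their 75th percentiles (58.9% higher, median log2 change 0.16), against 49.2% higher after quantile normalization. Of the 1198 probes, 47, 26 and 3 changed sign under those scalings, so that a count of higher against lower transcripts says little by itself, and changes are relative to the array as a whole.

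**Figure D1:**
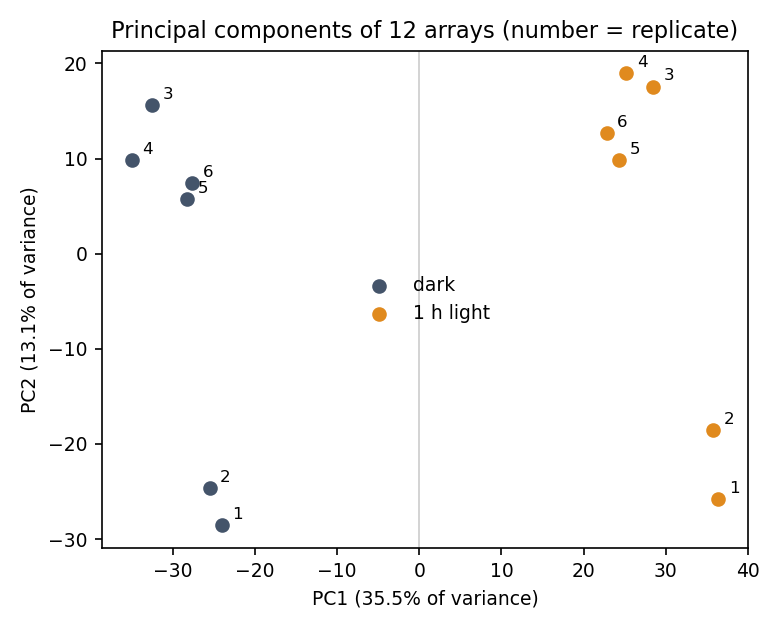
First and second principal components of the scaled log2 intensities of 12 arrays, with 6 dark and 6 light arrays in different colours and the replicate number beside each point. All 12 arrays lie on their own group's side of 0 on the first component, which holds 35.5% of the variance, and replicates 1 and 2 of both groups lie apart from the others on the second component, which holds 13.1%.

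The arrays grouped by light treatment. The first principal component held 35.5% of the variance and put 12 of 12 arrays on their own group's side of 0. The median correlation of log2 values across probes was 0.845 between arrays of the same group and 0.746 between arrays of different groups. Between columns of a consecutive pair of numbers it was 0.870. The second component held 13.1% of the variance and set replicates 1 and 2 of both groups apart from replicates 3 to 6.

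Of the 24 gene lists fixed before the data were examined, 8 had a member on a tested single-gene probe. They held 17 tested members, of which 6 were higher in light, 4 were lower and 7 did not pass. Among all single-gene probes tested, 42.8% passed, but among the 742 brightest probes of any kind 63.9% did. The list members that passed lay between the 53.3 and 99.7 percentiles of level, most of them at 89.9 or above. List members were not compared with probes of like level, so the number that passed does not mark these lists out. Adjusted over the list alone, the same 6 and 4 passed, but with 1 to 5 tested members per list this adds little support. With the consecutive numbers averaged, 6 of the 17 passed, 5 higher and 1 lower, so that 3 of the 4 lower calls were lost. The other 16 lists had no tested member, among them those for starch breakdown, flavonoid synthesis, dark-inducible genes, clock and photoreceptor genes, touch and wounding genes and markers of other cell types.

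In the photosystem I list, PSAN was the 1 member tested and rose. In the photosystem II list of 3 tested members, PSBY, a small membrane subunit, rose from 2.24 ± 0.28 to 4.16 ± 0.12 (log2 change 0.90, SE 0.11, adjusted p = 3.2e-05), PSBW fell, and PSB27, an assembly factor, did not pass (log2 change 0.01, SE 0.67, adjusted p = 0.996). The call for PSBY was lost on the values as deposited (log2 change 0.40, adjusted p = 0.063). The call for PSBW was lost with arrays centred on the 75th percentile (log2 change -0.40, adjusted p = 0.066), and its spot was at the top of the scale in 1 of the 6 dark arrays. PSB27 lay between 0.341 and 0.723 in replicates 1 and 2 of both groups and between 2.21 and 3.37 in the others, and without those replicates it was lower in light (log2 change -0.36, adjusted p = 0.033). In the light-harvesting list, LHCB1.5 was the 1 member tested on its own probe and rose. Of 8 tested probes that match several members of 1 list and no other gene, 2 passed, both higher in light, and 6 did not. The probe of the light-harvesting list was at 0.345 ± 0.006 in the dark and 1.54 ± 0.15 in light. The probe of the list of LHC-like proteins was at 0.397 ± 0.084 and 1.31 ± 0.25, while another probe with the same genes did not pass (log2 change 0.03, adjusted p = 0.85). In the Calvin cycle list, PRK was the 1 member tested.

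**Figure D2:**
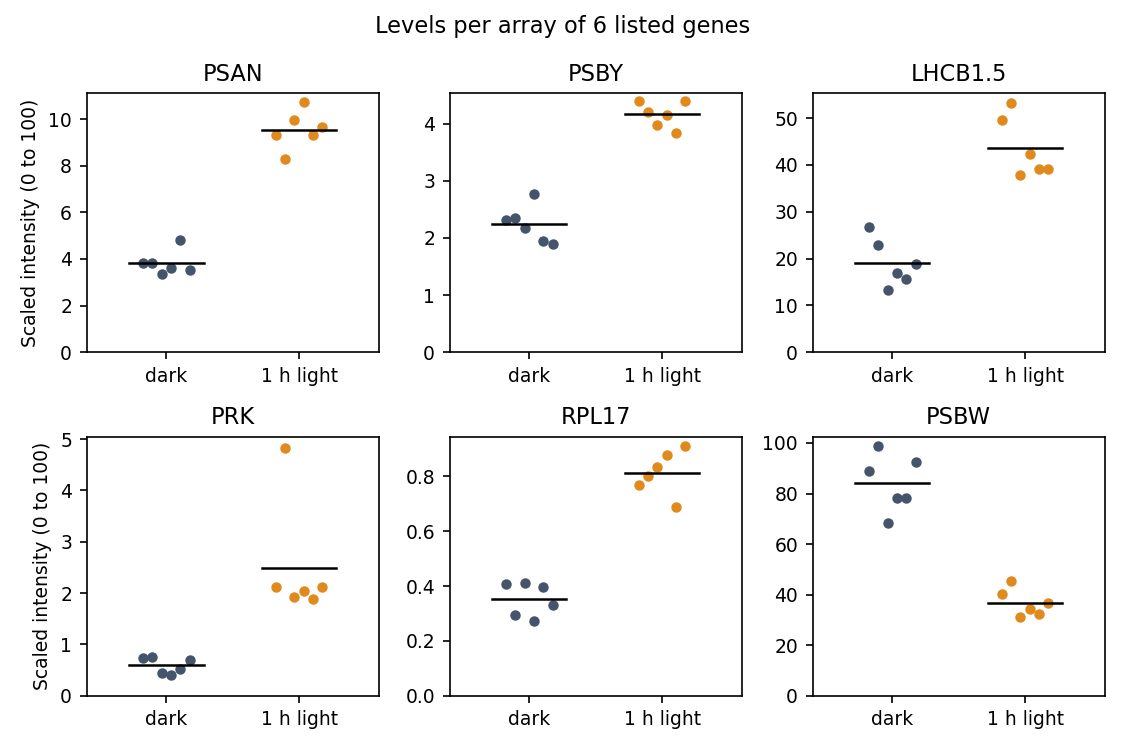
Scaled intensity, on a linear axis from 0, of 6 listed genes in each of 6 dark and 6 light arrays. Points are arrays and lines are means of 6; PSAN, PSBY, LHCB1.5, PRK and RPL17 lie higher in all light arrays than in any dark array, and PSBW lies lower.

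Both tested members of the chlorophyll and tetrapyrrole list changed, in opposite directions. CHLM, the magnesium protoporphyrin methyltransferase, rose from 0.262 ± 0.074 to 0.498 ± 0.124 (log2 change 0.95, adjusted p = 0.0067). CHLP (AT1G74470), the geranylgeranyl reductase that supplies the phytol tail, fell from 3.67 ± 0.24 to 2.80 ± 0.33 (log2 change -0.40, adjusted p = 0.012). With the consecutive numbers averaged neither passed (adjusted p = 0.061 and 0.11). CHLM was also lost without replicates 5 and 6 (adjusted p = 0.097) and CHLP without any 1 pair of numbers, and as deposited the log2 change of CHLP was -0.85. Of 5 tested plastid ribosomal proteins, RPL17 (AT3G54210) rose from 0.352 ± 0.011 to 0.813 ± 0.038 (log2 change 1.22, adjusted p = 1.6e-05), RPL29 (AT5G65220) fell from 2.07 ± 0.18 to 1.49 ± 0.14 (log2 change -0.48, adjusted p = 0.0034), and 3 did not pass. The single dark arrays of RPL17 ran from 0.272 to 0.412 and differed mostly within pairs, so its dark SD understates their spread. RPL29 was lost with the consecutive numbers averaged (adjusted p = 0.062) and without replicates 5 and 6 (adjusted p = 0.055), and its log2 change was -1.01 as deposited. As a set the ribosomal list did not differ from the other probes by limma's camera with a preset correlation (p = 0.88) or with an estimated correlation (p = 0.91). Its median log2 change was -0.01 and its mean 0.23, which differ in sign. In limma's fry, p was 0.24 for a shift in 1 direction and 8.3e-04 for change in either direction. Since fry does not compare a list with the other probes, and RPL17 and RPL29 passed singly, the second value does not mark this list out.

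Of 3 tested members of the antioxidant and thioredoxin list, NTRC, a plastid NADPH-dependent thioredoxin reductase, fell from 0.373 ± 0.001 to 0.256 ± 0.056 (log2 change -0.59, adjusted p = 0.021), and 2 did not pass. NTRC was lost with the consecutive numbers averaged (adjusted p = 0.092), with arrays centred on the 75th percentile (adjusted p = 0.055) and without any 1 pair of numbers. FATB, the plastid thioesterase that releases saturated fatty acids, was the 1 lipid synthesis gene tested and did not pass (log2 change -1.39, SE 0.90, adjusted p = 0.24), but did so without replicates 1 and 2 (log2 change -2.66, adjusted p = 0.014). It was dim, at 0.072 ± 0.029 in the dark and 0.031 ± 0.038 in light, and listed at 0 in 1 dark and 2 light arrays. With the floor at the 5% quantile its log2 change was -0.58, so that its size depended on the floor.

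The largest fitted rises among single-gene probes were those of DRT101, named for DNA damage repair and tolerance, and SRX, a sulfiredoxin that restores oxidised peroxiredoxins. DRT101 went from 0.064 ± 0.027 to 0.706 ± 0.160 (log2 change 4.26, SE 0.77, adjusted p = 9.4e-04), and was listed at 0 in 2 dark arrays. SRX went from 0.037 ± 0.019 to 0.443 ± 0.082 (log2 change 3.81, SE 0.53, adjusted p = 1.2e-04), and was listed at 0 in 1 dark array. With the floor at the 25% quantile of positive values (0.145) the log2 changes of DRT101 and SRX were 2.25 and 1.52 and both passed. The next 10 rises, with log2 changes from 3.76 to 2.36, were those of AT4G05030, AT5G25990, AT2G46910, AT1G56460, UGT74D1, which glycosylates auxin, AT4G33500, AT3G50270, AT4G16060, TPP2, a tripeptidyl peptidase, and AT1G68660. The falls taken by the same rule were those of AT4G38040, AT2G26110, AT2G06040, DI21, named for induction by drought, AT2G03140, AT3G47980, AT2G46300, AT1G72890, AT5G66090, AT2G31800, CUTA and AT5G27560 (log2 change -1.94, SE 0.19). AT4G38040 was at 0.200 ± 0.103 in the dark and listed at 0 in 4 of 6 light arrays, so that the floor set the size of its change (adjusted p = 0.0016), and it was tested in 19 of 29 other settings, not with the floor at the 5% quantile. DI21 fell from 0.427 ± 0.006 to 0.068 ± 0.031 (log2 change -2.85, SE 0.33, adjusted p = 3.3e-05).

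Many of these 24 genes were dim. Their median level lay at the 16.3 percentile of the probes tested, and 17 of them were listed at 0 in at least 1 array, so that the size of the change depended on the floor given to such values and their order carries no weight. With the floor raised to the 25% quantile of positive values, 14 were still tested and 13 passed, all but AT3G47980 (adjusted p = 0.058), but their median size went from 2.49 to 1.52 on the log2 scale. With the consecutive numbers averaged 20 of the 24 passed, and AT4G33500, AT2G26110, AT1G72890 and AT2G31800 did not (adjusted p = 0.075, 0.17, 0.058 and 0.056). The call for AT2G26110 was also lost when any of 6 single arrays was left out (adjusted p from 0.051 to 0.056). With arrays centred on the 75th percentile, AT1G72890, AT2G03140 and AT3G47980 did not pass (adjusted p = 0.084, 0.055 and 0.052). Leaving out 1 pair of consecutive numbers from both groups also ended the calls of AT2G46910, UGT74D1, TPP2, AT1G68660 and AT2G06040.

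Brighter genes were therefore also taken, by a rule set after the values were seen. Among 157 tested single-gene probes above the 75th percentile of levels, 34 changed more than 2-fold, passed with all arrays and with consecutive numbers averaged, and were never at 0. Of these 14 were higher and 20 lower in light. All 34 kept their direction under the other scalings, but 26 were over 2-fold as deposited, 28 with median centring, 26 with 75th percentile centring and 31 with cyclic loess. The highest rise was that of AT1G32730, from 0.912 ± 0.125 to 4.36 ± 0.22 (log2 change 2.27, SE 0.11, adjusted p = 2.6e-08). AT3G47650, which encodes a protein with a DnaJ-type zinc finger, rose from 0.651 ± 0.108 to 2.71 ± 0.15 (log2 change 2.07, SE 0.13, adjusted p = 2.4e-07). PRA1.B6 rose from 3.62 ± 0.77 to 9.94 ± 0.72 (log2 change 1.48, SE 0.13). PIFI, a factor of chlororespiration, rose from 0.418 ± 0.080 to 0.865 ± 0.015 (log2 change 1.06, SE 0.13), with a log2 change of 0.60 as deposited.

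Among the bright genes that were lower in light, CCL fell from 12.6 ± 2.1 to 3.98 ± 0.30 (log2 change -1.67, SE 0.19, adjusted p = 2.2e-05). CCL is known as a transcript whose decay is under clock control. HISN4 (AT4G26900), an enzyme of histidine synthesis, fell from 1.099 ± 0.069 to 0.304 ± 0.038 (log2 change -1.87, SE 0.12, adjusted p = 2.4e-07). AT4G32060 fell from 5.83 ± 1.01 to 1.53 ± 0.23 (log2 change -1.92, SE 0.14, adjusted p = 6.4e-07). XERICO, a RING-type protein that acts in abscisic acid accumulation, fell from 2.24 ± 0.38 to 0.849 ± 0.139 (log2 change -1.40, SE 0.14, adjusted p = 1.0e-05). NdhS, a subunit of the plastid NAD(P)H dehydrogenase-like complex, fell from 10.0 ± 0.8 to 5.01 ± 0.25 (log2 change -1.0005, SE 0.09, adjusted p = 3.8e-06). AT2G27290 fell from 74.8 ± 14.7 to 31.2 ± 3.5, and its log2 change went from -1.25 to -0.44 with arrays centred on the 75th percentile (adjusted p = 0.036).

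**Figure D3:**
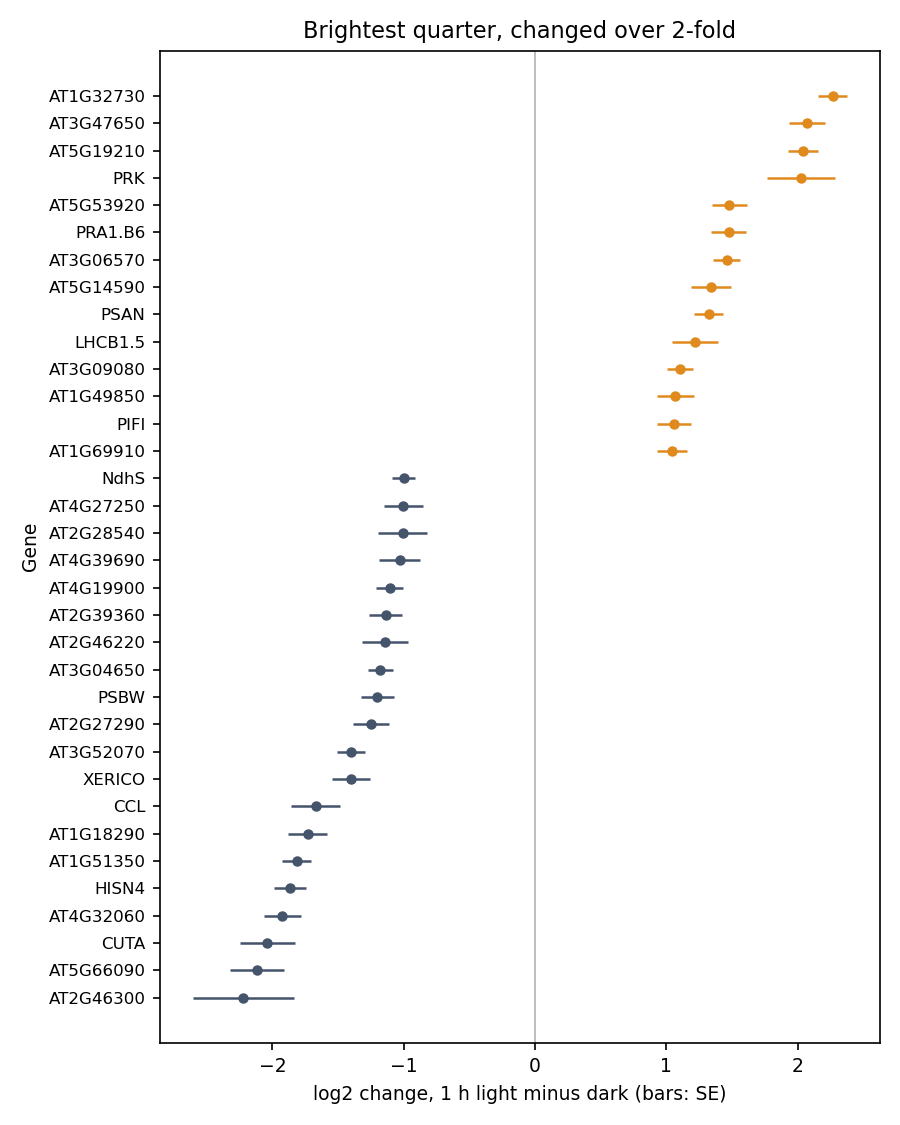
Change in 1 h light relative to dark, on the log2 scale with bars for SE, of 34 single-gene probes above the 75th percentile of levels that changed more than 2-fold. The 14 higher genes run from 1.04 to 2.27 and the 20 lower genes from -1.0005 to -2.22.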

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

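Apart from the count over splits of the 12 arrays, the tests in this part were chosen after the result was seen. Among 164 sets of 6 values, 15 held a sample that lay far from the others relative to the range of its group. Chance gives this in about 1 set in 20, and several of these sets lie at the floor, where most values are tied. On the log2 scale, PRK in light replicate 2 was at 2.27 against a median of 1.03 in the others, and PSAN in dark replicate 5 was at 2.27 against 1.86. NdhS in light replicate 6 was at 2.11 against 2.36, HISN4 (AT4G26900) in light replicate 3 at -2.23 against -1.62, and AT2G46300 in light replicate 1 at -3.58 against -1.13. AT2G31800 was at -1.96 in dark replicate 4 against -0.94, and at -6.31 in light replicate 4 against -2.51. AT2G04700, which encodes a ferredoxin-thioredoxin reductase subunit and did not pass, was at -3.51 in light replicate 2 against -2.004, and without that array it passed (log2 change 0.92, adjusted p = 0.0035). SIRB in dark replicate 2 was at -5.18 against -3.14, and AT5G39980 in dark replicate 3 at -1.78 against -2.35. At or near the floor, AT4G38040 was at -7.21 in dark replicate 2 against -2.004 and at -6.53 in light replicate 5, AT1G56460 at -4.38 in dark replicate 2, AT2G06040 at -4.04 in light replicate 6, and AT2G03140 at -4.16 in light replicate 4, the last 4 against a median of -7.21.

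If the 12 arrays are separate samples, chance division of them can be excluded for the count of changed probes. Of 100 of the 462 splits of the 12 arrays into 6 and 6, 1 gave as many as the real one, namely the real split with 1198, and the highest other gave 1. Among the 32 splits that part the dark and light array of each number, the highest other also gave 1. Of these 32, 4 keep the pairs of consecutive numbers together, the real one included, and the highest other of them gave 0. So few splits cannot give a share under 0.05. The rest of the 32 break these pairs, as do most splits of the 12 arrays. With the number pairs averaged, the 6 pair means have 10 splits into 3 and 3, too few for a share under 0.05. The real one gave 814 probes, the highest other 0, and 1 of the 10 was as large.

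The columns of a group with numbers 1 and 2, 3 and 4, and 5 and 6 were alike. This pairing had the smallest spread in 2 of 2 groups. A filter, RNA or plant batch shared by the columns of a pair would give this. The spread restates the likeness that prompted the test, however, so it does not decide on a cause. Whether a shared RNA or plant batch is the only link between dark and light columns of a number cannot be told apart from spots or filters used for both treatments. The dark column correlated more with the light column of its own number than with that of its partner's, by 0.27 on average over 3 number pairs (SD 0.25), but the difference was 0.56 for numbers 1 and 2, 0.09 for 3 and 4 and 0.16 for 5 and 6. Whether the columns of a pair hold separate plants also stays open.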

How the results depend on the processing

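The pair means, the random block, the 25% floor and leaving out pairs of numbers were chosen after seeing the data. The count of changed probes stayed within 1.5 times of 1198 under all 29 settings. It was 1314 with the replicate block (641 higher, 673 lower; 1137 of the 1198 kept), 814 with number pairs averaged, and 1094 to 1174 leaving out 1 array. The 78 named genes gave 2214 values under these settings, of which 2107 kept direction and side of the threshold, 67 lost the call, 7 gained it and 33 changed sign. Of the 71 that passed, 51 passed under all settings they were tested in and none changed sign. The replicate block changed the call of AT2G04700 (adjusted p = 0.025) and no other named gene. Calls among list members numbered 10 and fell to 6 with number pairs averaged and to 6 without the third pair; the cause was not tested, though fewer values enter both. Leaving out 1 array gave 10 to 11. The first component separated all arrays kept in each setting where it was run. The camera p of the ribosomal list, which did not pass anywhere, turned from higher to lower with the replicate block (0.99), without the first pair (0.9990) and without light replicate 2 (0.946), and ranged from 0.639 to 0.9985 leaving out 1 array. It was not run with the trend and robust fit, array weights, pair means or random block, and the 25% floor and the filter on the dimmest 25% of probes left fewer than 5 members.

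All sign changes among genes were in 4 that did not pass, and their cause was not tested. PSB27 went from 0.01 to -0.43 as deposited, -0.31 with median centring, -0.058 with 75th percentile centring, -0.0021 with array weights and -0.36 without the first pair, and to between -0.44 and 0.25 leaving out 1 array. AT3G52960, a peroxiredoxin, went from -0.09 to 0.011 as deposited, 0.13 with median centring, 0.38 with 75th percentile centring, 0.20 with the 5% floor, 0.12 with array weights, 0.17 with the 25% floor, 0.39 without the first pair and 0.089 without the second, and to between -0.50 and 0.64 leaving out 1 array. RPL5 (AT4G01310) went from -0.01 to 0.093 with 75th percentile centring, 0.031 with cyclic loess, 0.026 with array weights and 0.080 without the second pair, and to between -0.13 and 0.14 leaving out 1 array. RPS10 (AT3G13120) went from -0.41 to 0.10 with 75th percentile centring. Of the dimmest 25% of probes 22.2% passed, and of the brightest 63.9%; whether dim signal or fewer changes accounts for this was not tested.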

Other observations

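All tests in this part were chosen after the values were seen. A further 3 lists were made from the annotated genes once their values were known, so their counts are not independent evidence. Among 13 tested genes of photosynthetic complexes and their assembly or accessory factors, 6 were higher and 4 lower in light (camera p = 0.30, and 0.30 with an estimated correlation). Beside the genes already described, RIQ2 (AT1G74730), which acts in grana stacking, rose from 0.199 ± 0.022 to 0.395 ± 0.060 (log2 change 0.99), and PPD3 (AT1G76450), a PsbP domain protein, fell from 13.1 ± 2.1 to 7.004 ± 0.796 (log2 change -0.89). CCB3, which acts in cytochrome b6 maturation, was higher (log2 change 0.63, adjusted p = 0.019) and PYG7 (AT1G22700), a photosystem I assembly factor, lower (log2 change -0.81, adjusted p = 0.027), but neither call was firm. Both were lost with number pairs as a random block (adjusted p = 0.053 and 0.068) and without the second pair of numbers. CCB3 was also lost without the first pair and with the trend and robust fit (adjusted p = 0.075), and PYG7 without the third pair, without dark replicate 3 (adjusted p = 0.0502) and without light replicate 6 (adjusted p = 0.056).

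Among 14 tested pentatricopeptide repeat proteins, a family that binds organelle RNA, 3 were higher and 5 lower (limma camera, adjusted p = 0.75). With number pairs averaged 2 higher and 2 lower were left. AT3G26630 rose from 15.7 ± 0.8 to 27.7 ± 3.6 (log2 change 0.81) and AT5G39980 by 0.89 on the log2 scale, while AT4G21170 fell from 0.995 ± 0.098 to 0.606 ± 0.100 (log2 change -0.73). Of 6 tested genes for amino acid, sulfur and cofactor synthesis, 1 was higher and 3 lower (camera p = 0.15, and 0.30 with an estimated correlation). SIRB, which inserts iron in siroheme synthesis, rose from 0.095 ± 0.021 to 0.333 ± 0.063 (log2 change 1.93), and HISN4, APS4, an ATP sulfurylase (log2 change -1.42), and THIC, an enzyme of thiamine synthesis (log2 change -0.51), fell. THIC was lost with number pairs averaged (adjusted p = 0.097, and 0.061 with a pair block), with arrays centred on the 75th percentile (log2 change -0.33, adjusted p = 0.092) and without the second pair or the third. Adjusted over the 3 lists, the lowest camera p was 0.44. In limma's fry, which does not compare a list with the other probes, p for a shift in 1 direction was 1.8e-04 for the photosynthetic list (higher). It was 2.5e-04 for the amino acid, sulfur and cofactor list (lower) and 0.61 for the pentatricopeptide list. The members of these lists were chosen with their values known, so these p-values carry no independent weight.

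The share of higher calls depended on the scaling. A single scale factor per array, as scaling to the brightest spot would leave, is argued against, since it would shift all percentiles alike. Over the 6 numbers the 25th percentile of the deposited values was higher in light by 0.26 (SD 0.10) on the log2 scale and the 75th percentile changed by -0.37 (SD 0.07), a difference of -0.62 (SD 0.11). The 90th percentile changed by -0.60 (SD 0.07) and the 99th by -0.08 (SD 0.09), so the shift did not grow steadily with level. The shape of the distribution thus differed between treatments. A change in background or in the RNA population stays open and was not tested.

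Probes that list the same several genes showed little common change. Over 62 such probe pairs, each taken in both orders, the correlation of log2 changes across pairs was 0.16 (95% bootstrap interval -0.05 to 0.34, Spearman 0.18, permutation p = 0.20). The SE of the changes would leave a correlation of up to 0.82. Of 8 pairs in which both probes passed, 5 moved in the same direction. This argues against the hypothesis that both probes measure the same mixture of transcripts. That each probe reads mainly 1 of the genes it lists, or that some names of this old annotation are wrong, stays open and was not tested.

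The spot of AT4G17070 was at 16.4 in dark replicate 1 against 35.7 to 42.2 in the other dark arrays, and at 7.88 in light replicate 1 against 17.2 to 19.8 in the other light arrays, as deposited.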
